A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

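Polyadenylated 3′ ends of total RNA were sequenced from the fission yeast Schizosaccharomyces pombe, with 1 library from a strain in which the nmt1 promoter drives seb1 (nmt1-SEB1) and 1 library from a wild-type strain. Per the labels, both cultures grew in minimal medium with thiamine, which represses the nmt1 promoter. The labels call the first strain a knock-out in some fields and the series design calls it a knockdown, so it is named here by its promoter construct. With 1 library per group there was no replicate check, and every test on reads below compares the 2 libraries, not the conditions.

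The deposited values are counts: for each library, the authors gave the number of poly(A) site-supporting (PASS) reads that end at each genomic position and strand, with no normalization. Reads were aligned with Bowtie2 to the assembly ASM294v2, per the submitters' processing notes; the version of Bowtie2 and the read filters are not given in the sources used here. The protocol text in the labels speaks of RPM, but the values are whole numbers whose sums differ between the libraries, so they were treated as counts. PASS reads carry untemplated A residues, which limits but does not remove priming inside genomic A runs. The protocol text names no molecular identifiers, and PCR copies of a molecule would be counted as separate reads, so all intervals and floors given here cover counting error only.

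Gene models came from the RefSeq annotation of the reference genome given with the data, whose chromosomes I, II and III carry the coordinates used. Of the reads assigned to coding genes, 40.4% in nmt1-SEB1 and 42.0% in wild type ended within 25 nt of an annotated 3′ end on the same strand. Whether the deposited positions count from 0 or from 1 was not stated, so positions are given as deposited and could be off by 1 nt. Reads on 3 other contigs were left out of the gene counts and are given only as totals.

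A read was assigned to the gene on its strand that contains it. Where several genes contained it, the gene with the nearest annotated 3′ end took it, and a read in no gene went to the gene ending up to 1000 nt upstream, as far as the start of the next gene on that strand. Long non-coding RNAs (lncRNAs) counted as genes. Abundance was expressed as RPM over gene-assigned reads, where 1 read was worth 0.301 in nmt1-SEB1 and 0.372 in wild type. The ratio of nmt1-SEB1 over wild type carries an exact conditional binomial (Clopper-Pearson) 95% interval. Among genes with 20 or more reads summed over both libraries, a gene was counted as higher or lower when its ratio was at least 2 or at most 0.5 and the interval excluded 1. A library with 0 reads was set to a floor of 3 counts where a fold was printed; such a fold leaves out the counting error of the other library and can lie beyond the limit of the 95% interval.

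For poly(A) site choice, the reads of each coding gene were taken from the stop codon to 1000 nt past the annotated end or to the next gene start on that strand. The position with the largest share, averaged over the libraries with equal weight, gathered all positions within 24 nt, and the step was repeated on the rest. The 2 clusters with the largest mean share were called proximal and distal; each needed 5% of the gene's reads in at least 1 library, and the pair needed 20 reads in each library. Distal shares carry Wilson 95% intervals. The distal shares were compared with a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over all genes tested, and a gene was counted as shifted when the adjusted p was under 0.05 and the shares were at least 10 percentage points apart. The mean distance of reads past the stop codon was compared for genes with 20 or more reads in each library, and genes 20 nt or more apart were counted without a test. Read-through was the share of reads more than 200 nt past the largest cluster of the gene, and the share more than 200 nt before it is given beside it. Nuclear reads were sorted into annotation classes in 1 fixed order, so that each read fell into 1 class. Poly(A) signals (AATAAA or AATGAA) were searched in the 50 nt before each cluster, and TGTA and GTA in the 100 nt after it; 3 control motifs with the bases of TGTA in another order were added after the TGTA values had been seen.

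Gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The lists were cytosolic ribosomal proteins, snoRNAs, snRNAs, histones, stress response, phosphate, thiamine, meiotic genes regulated by Mmi1 and the exosome, mating and pheromone, sporulation, iron uptake, copper uptake, hexose transport and glucose repression, glycolysis, cleavage, polyadenylation and termination factors, nuclear surveillance, heterochromatin factors, amino acid synthesis, coding genes within 50 kb of an end of chromosome I or II, Tf2 elements, mitochondrially encoded genes and intron-containing genes. A list is described by its counts, by its median log2 ratio minus the median of all coding genes, and by the percentile of its median among 10000 random lists of the same size matched on abundance. The named genes were seb1, the 8 highest and 8 lowest ratios among counted coding genes with 100 or more reads, the 2 members of each list furthest from 0, the 10 largest distal and 5 largest proximal shifts with 100 or more reads per library, and the snoRNA genes and 7 others fixed in advance. Genes named outside this rule are said to be so.

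Alternatives were TMM factors and median-of-ratios size factors, other read minimums, a 200 nt or 500 nt limit past the gene end, thinning the deeper library to the depth of the other, leaving out sites next to genomic A runs (6 A in a row, or 7 among the 10 nt downstream), other cluster widths, other choices of the clusters and other read-through distances. Ignoring lncRNA annotations, counting only reads past the stop codon, and thinning for the mean position and read-through were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and the TMM shift was the same to 3 digits as that of edgeR 4.0.16. The procedures were tested on simulated data that held counting error alone, with no variation between cultures, library preparations or PCR copies. For gene abundance (7598 genes), 16% of genes set 1.5-fold apart, which is below the 2-fold limit, 94.0% of genes set 3-fold apart, 98.0% of those set 4-fold apart and 0.730% of 7398 unchanged genes were counted. For poly(A) site shift (2772 genes), a move of 30 percentage points was recovered in 92.2% of genes with 100 or more reads in each library and in 51.1% of those below, and 4 of 2581 unchanged genes were counted. For mean poly(A) position, simulated for genes of the site test only, 308 of 2743 unchanged genes came out 20 nt or more longer and 314 shorter.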

Results

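Poly(A) site reads were counted genome-wide in 2 fission yeast libraries, nmt1-SEB1 and wild type, with 1 library per group. Seb1 is an RNA-binding protein related to budding yeast Nrd1, and the series asks how it affects 3′ end processing and the choice of poly(A) site. The nmt1-SEB1 library held 3376142 reads at 213060 positions and the wild-type library 2702105 reads at 114578 positions. With both libraries at 2697953 nuclear reads, 190644 and 114474 positions remained. Genes took 98.4% and 99.6% of all reads mapped to the 3 nuclear chromosomes, and the largest single gene was gpd3 in nmt1-SEB1 (9.81% of gene reads) and rpl301 in wild type (7.71%). None of the differences below has a replicate check.

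The targeted gene was lower in the nmt1-SEB1 library. seb1 (SPAC222.09, chromosome I, 959885 to 962227, plus strand) had 826 reads against 1848, a ratio of 0.362 (95% interval 0.333 to 0.393) and a log2 ratio of -1.47. The reads of seb1 also ended further downstream. The distal of its 2 clusters, 424 nt past the stop codon, held 34.8% of the reads in both (Wilson interval 30.9 to 38.8) in nmt1-SEB1 and 0.0597% (0.0105 to 0.337) in wild type, and 52.7% against 2.82% of its reads lay more than 200 nt past its main cluster. With reads counted only up to 200 nt past the gene end the log2 ratio was -2.36, and with clusters of 10 nt, which took another pair of sites, the distal share was lower in nmt1-SEB1 (difference -11.1 points).

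Coding genes used their distal poly(A) cluster more in the nmt1-SEB1 library. Of 2943 genes tested, 1984 (67.4%) had a higher distal share there, 117 (3.98%) a lower one and 842 neither, by Fisher's exact test with Benjamini-Hochberg adjustment and a difference of at least 10 points. The median distal share was 65.3% in nmt1-SEB1 and 16.9% in wild type, and the median difference was 25.5 points. Differences of 50 points or more were seen in 766 genes with a higher distal share and 12 with a lower one. The test compares the reads of these 2 libraries, not the conditions. With the pair of clusters chosen on wild type alone, 1218 genes had a higher distal share.

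In the 10 genes with the largest differences among those with 100 or more reads in each library, nearly all reads of the 2 clusters compared lay in the proximal one in wild type and in the distal one in nmt1-SEB1; reads at other sites are left out of these shares. eca39, a branched-chain aminotransferase gene, had 226 of the 227 reads of its clusters in the distal one in nmt1-SEB1 (99.6%, Wilson interval 97.5 to 99.9) and 0 of 327 in wild type, which allows up to 1.16% (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.03e-158). For tkt1, which encodes transketolase, the distal cluster 400 nt past the stop codon held 97.5% against 0.440%. In rps1901, which encodes ribosomal protein S19, the shares were 98.0% and 1.09% at 281 nt past the stop codon, where the proximal cluster lay at 45 nt. uvi15 (96.8% against 0%, with a wild-type upper bound of 2.40%), mep33 (96.0% against 0.431%) and nde1, a mitochondrial NADH dehydrogenase gene (97.5% against 2.39%), had the same form. So did the Rab GTPase gene ypt2 (97.9% against 2.96%), the fimbrin gene fim1 (96.0% against 1.58%), wos2 (99.6% against 5.62%) and rpl22 (98.0% against 4.29%). Chosen on wild type alone, the clusters of tkt1, mep33, ypt2 and wos2 left out the distal site, and these 4 genes no longer passed.

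**Figure D1:**
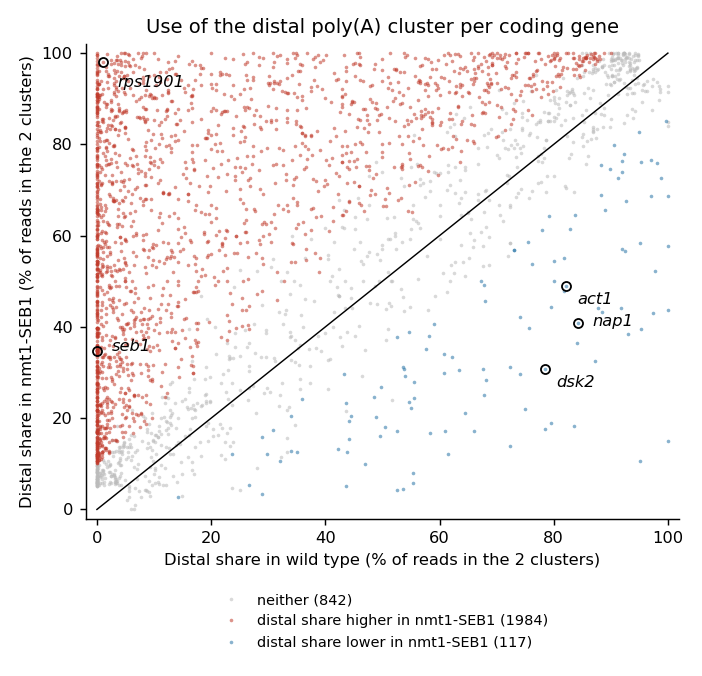
Each point is 1 of 2943 coding genes, with the distal share of its reads in wild type on the x axis and in nmt1-SEB1 on the y axis, both in percent of the reads in its 2 clusters; the line marks equal shares. Most points lie above the line, 1984 of them counted as higher in nmt1-SEB1 and 117 as lower.

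A lower distal share was less common, and 68 of these 117 genes had a higher share of reads more than 200 nt past the main cluster in nmt1-SEB1. So did 502 of the 842 genes with neither call and 1382 of the 1984 with a higher distal share. Among genes with 100 or more reads in each library, the 5 largest differences were those of dsk2, a ubiquitin receptor gene (30.8% against 78.5%), SPBC8D2.18c (29.6% against 74.0%), the histone chaperone gene nap1 (40.9% against 84.2%), the casein kinase gene hhp1 (28.4% against 68.1%) and apm4 (5.22% against 43.7%). The actin gene act1, fixed in advance, had 49.0% against 82.2%. Reads more than 200 nt past the main cluster made up 56.2% against 0.376% of dsk2, 36.0% against 0.0654% of SPBC8D2.18c and 33.6% against 2.75% of act1, and the mean end of these 3 genes lay 120, 126 and 50.2 nt further downstream in nmt1-SEB1. The mean end lay further upstream for nap1 (difference -127 nt), hhp1 (-101 nt) and apm4 (-225 nt). With the first and last clusters of 5% or more compared instead, the distal share was higher in nmt1-SEB1 for dsk2, SPBC8D2.18c, nap1 and act1. Of the 117 genes, 49 had a longer and 44 a shorter mean position.

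**Figure D2:**
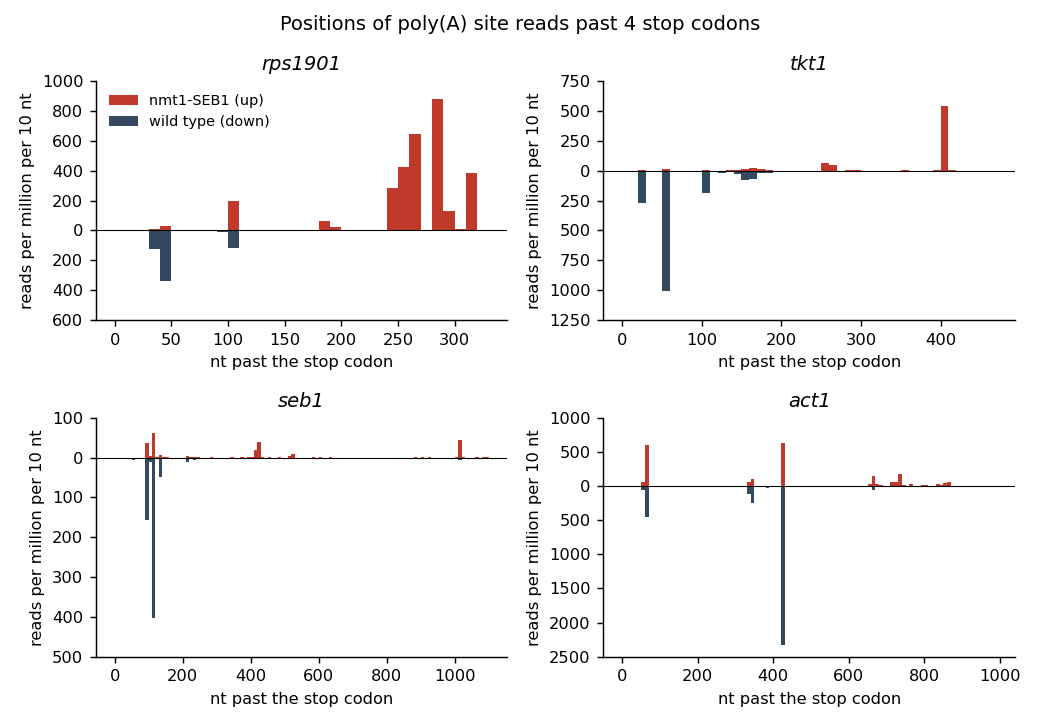
RPM over gene-assigned reads in bins of 10 nt past the stop codons of rps1901, tkt1, seb1 and act1, with nmt1-SEB1 upward and wild type downward. In rps1901 and tkt1 the compared distal clusters of nmt1-SEB1 lie near 281 and 400 nt past the stop codon, with reads at other sites as well, while act1 has reads in both its clusters and, in nmt1-SEB1, more beyond them.

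The mean poly(A) position lay further from the stop codon in nmt1-SEB1 for 2728 of 3672 genes (74.3%), and closer to it for 104 genes, with 840 genes within 20 nt. The median difference was 65.9 nt (quartiles 18.8 and 157), and the medians of the gene means were 306 nt and 201 nt. This count has no test behind it. In simulated unchanged data, which held counting error alone, 308 of 2743 genes came out longer and 314 shorter. Read-through more than 200 nt past the main cluster took 10.4% of reads (Wilson interval 10.3 to 10.4) in nmt1-SEB1 and 1.14% (1.13 to 1.15) in wild type. As a mean over genes the shares were 17.2% and 3.53%, and 1445 against 376 genes had more than 10% of their reads there. Reads more than 200 nt before the main cluster had a mean share of 3.23% in nmt1-SEB1 and 8.59% in wild type; where the main cluster is the distal one, they include reads of the proximal site, so they are no independent control.

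Genes with a tandem and with a convergent neighbour downstream were alike in direction. Among 1276 tandem genes tested, 868 had a higher and 54 a lower distal share in nmt1-SEB1, and among 1667 convergent genes 1116 and 63. Mean read-through was 14.5% against 3.01% for tandem genes and 19.3% against 3.94% for convergent genes; the difference between the classes was not tested, and reads of tandem genes are counted only up to the next gene. Phosphate genes, known to respond to transcription of upstream lncRNAs, also had higher distal shares. The distal share was 38.7% against 0.0503% for the acid phosphatase gene pho1, 42.2% against 12.9% for the phosphate transporter gene pho84 and 68.5% against 4.88% for tgp1, which lost its call under 3 alternatives (clusters of 50 nt, clusters chosen on wild type alone, and thinning), where its difference fell from 63.6 points to 15.6, 15.5 and 14.0 (adjusted p from 0.0883 to 0.148 by Fisher's exact test). nmt1 and adh1 had too few reads in wild type for the test, with 9 and 18 reads past the stop codon.

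Reads outside the 3′ ends of coding genes took a larger share in nmt1-SEB1. Of all nuclear reads, 73.8% in nmt1-SEB1 and 93.2% in wild type ended in a 3′ UTR or up to 200 nt past a coding gene. Annotated non-coding RNA held 8.84% against 2.46%, regions antisense to a gene 9.44% against 1.09%, and other intergenic regions 4.92% against 0.887%. Coding sequence differed little, at 1.60% and 1.5%, while introns held 0.342% against 0.246% and 5′ UTRs 1.08% against 0.597%. The Wilson intervals of these shares did not overlap between the libraries. On the strand opposite a coding sequence, whatever else is annotated there, lay 10.9% against 2.41% of reads. A read more than 200 nt past a coding gene falls into the non-coding, antisense or intergenic class, unless another coding gene on its strand takes it. These shares therefore overlap with the read-through given above and are no separate result. The size of the overlap was not counted.

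**Figure D3:**
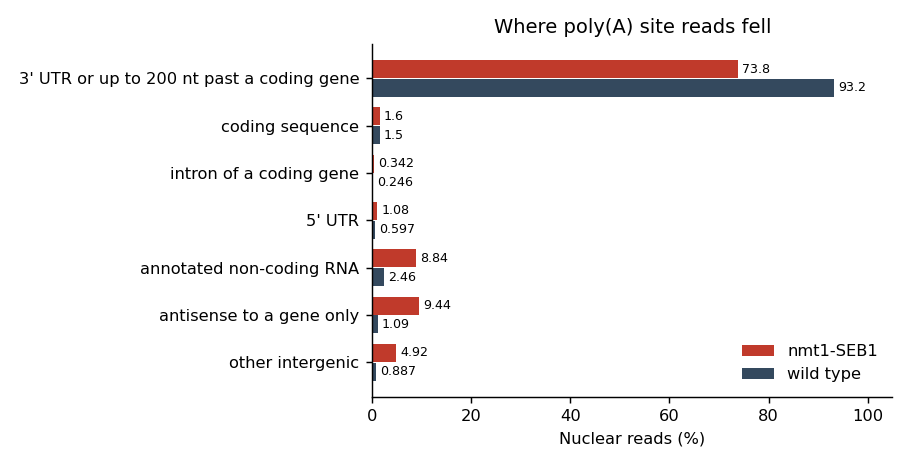
Percent of nuclear reads in 7 annotation classes, with nmt1-SEB1 and wild type as bars from 0. The 3′ ends of coding genes held 73.8% and 93.2%, and the antisense, non-coding and intergenic classes were larger in nmt1-SEB1.

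Non-coding RNAs followed the same direction. Of 2840 lncRNAs tested, 2269 were at least 2-fold higher in nmt1-SEB1 and 93 lower (1941 and 174 under TMM, 1903 and 191 under median-of-ratios), their median log2 ratio was 2.67 above that of coding genes, and they took 13.9% against 3.43% of gene reads. The size of that lncRNA difference depended on the read minimum: it was 1.23 with no minimum and 3.28 with 100 reads. Of 7133 annotated lncRNAs 2840 were tested, and a lncRNA could pass through the reads of 1 library alone. Tested lncRNAs overlapping or within 2000 nt downstream of a gene of another class on their strand held 340725 against 58212 reads. The rest held 102610 against 30414. Reads past a coding gene that reach a lncRNA are assigned to it, so the lncRNA share overlaps with the read-through given above. Of 31 tRNA genes, 22 were higher and none lower (14 and 1 under TMM, then 13 and 1 under median-of-ratios). Among 38 snoRNA genes, which guide RNA modification, 25 were higher and 1 lower (14 and 2, then 12 and 2), with 0.460% against 0.143% of gene reads. Of the 29 tested in the snoRNA list, 19 were higher and 1 lower (10 and 2, then 8 and 2), with neither call for sno1, a coding gene that the symbol rule took in; the list's median lay at the 0.0400 percentile of random non-coding lists, that is, it was less high than other non-coding RNAs. snR93 had 1696 against 26 reads (log2 5.72), with 99.2% of the nmt1-SEB1 reads and all 26 wild-type reads more than 20 nt past its end; it lies just downstream of rpl29, which was lower (log2 -3.57). The excess of snoR02 (log2 5.12) lay almost wholly more than 200 nt past its end, 213 of 215 reads, and its log2 ratio was -0.17 without them. sno12 (log2 4.52), SPNCRNA.814 (3.56), SPNCRNA.1394 (3.44) and snoR69 (3.31) were also higher. Of their nmt1-SEB1 reads, 97.0%, 93.8%, 81.9% and 72.1% ended more than 20 nt past the annotated end. In wild type, with 18, 10, 14 and 10 reads, the shares were 94.4%, 30%, 0% and 90%. snR95 (-0.81) was below 2-fold but was lower by more than that under TMM (-1.49) and median-of-ratios (-1.60). Over the 23 snoRNA genes with 100 or more reads, reads more than 20 nt past the annotated end made up 60.4% in nmt1-SEB1 and 52.9% in wild type. snoR61, with the most reads among them (5103 and 1339), had only 1.74% and 0.82% there, which lowers both pooled shares. Over the 4 snRNA genes with 100 or more reads the shares went the other way, at 17.6% and 41.2%, or 33.4% and 38.2% without snu2. The snRNA list had 6 of 6 tested members higher (5 under TMM and under median-of-ratios; percentile 67.5 of random non-coding lists), namely 4 snRNA genes and, taken in by symbol, the U3 snoRNA genes snu3 and snu32. snu2 had 3584 against 17 reads (log2 7.42). Of its nmt1-SEB1 reads, 92.1% ended at 1 position 1 nt from its annotated start. Such reads hold almost none of snu2, so this ratio is no measure of snu2 RNA. snu5 had 1165 against 35 reads (log2 4.75).

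Sequence after the proximal cluster differed between genes with and without a shift. TGTA, the DNA form of the UGUA element, occurred within 100 nt after the proximal cluster in 68.5% of the 1984 genes with a higher distal share in nmt1-SEB1, in 50.8% of the 842 with neither call and in 35.0% of the 117 with a lower one. Of random lists matched on reads, 95% lay between 61.4% and 63.8%, and the first list lay above all 10000 of them. GTA, the element known from Nrd1-like proteins, occurred in 93.9%, 81.0% and 58.1%. After the distal cluster TGTA was less frequent in genes with a higher distal share, at 56.5% (95% of random lists between 57.2% and 59.7%). It occurred there in 60.9% of the genes with neither call and in 67.5% of those with a lower distal share. The control motifs TTGA, GATT and AGTT lay at percentiles 39.7, 69.6 and 95.6 after the proximal cluster. Poly(A) signals before the proximal cluster stood at 25% (percentile 17.1) and before the distal one at 30.8% (percentile 99.2). The classes differ in other ways too. The median distance between clusters was 159 nt (higher), 76 nt (neither) and 239 nt (lower), so the 100 nt window can run past the distal cluster. In genes with a lower share, such as act1, wild type could use the distal cluster most (82.2%). Random lists were matched on reads alone, so these differences were not separated from the shift.

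Coding gene abundance differed in both directions. Of 4701 coding genes tested, 1223 were at least 2-fold higher and 798 lower in nmt1-SEB1, so 60.5% of these calls were higher. This split depends on the scaling, since TMM moved every log2 ratio by -0.68 and median-of-ratios by -0.79, which gave 650 higher and 1549 lower (29.6% higher) and 575 higher and 1700 lower (25.3% higher). It also depends on how reads are assigned to genes. With lncRNA annotations ignored, 1481 of 4748 coding genes tested were higher and 627 lower (70.3% higher). Of all 7633 genes, 3554 were higher and 892 lower. Directions below held under the 3 scalings for every gene whose log2 ratio exceeded 1 in size, but a positive value less than 0.79 above 1 was below 2-fold under median-of-ratios, and a negative value less than 0.79 short of -1 was beyond 2-fold. For gene lists, the numbers higher and lower under TMM and then under median-of-ratios follow in brackets. Among higher coding genes, 16.1% had under 50% of their nmt1-SEB1 reads past the stop codon, against 8.27% of lower ones.

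The highest ratios belonged to adh1, an alcohol dehydrogenase gene with 7710 against 21 reads (297-fold, interval 194 to 481), meu14, with 1722 against 5 (279-fold, 119 to 860), and zym1, a metallothionein gene with 1826 against 8 (185-fold, 93.6 to 429, or log2 7.53, which fell to 5.83 with reads up to 200 nt past the gene end). lsb1 (456 against 2 reads, ratio 185, interval 50.8 to 1530) and the splicing factor gene prp38 (745 against 5, 121-fold) were also higher. SPAC637.03 had 26200 against 182 reads (log2 6.87, or 2.93 with reads up to 200 nt past the gene end). Of the nmt1-SEB1 reads of meu14, new25 (749 against 5) and SPCC191.04c (580 against 4), only 0.465%, 3.47% and 0.172% lay past the stop codon; with such reads alone the log2 ratios were 0.71 (interval -1.19 to 2.89), 3.41 (1.42 to 6.53) and -0.29 (-6.58 to 6.01), which ends the calls of meu14 and SPCC191.04c. The lowest ratios were those of adh4, another alcohol dehydrogenase gene (35 against 3281 reads, log2 -6.85), SPAC13C5.05c (3 against 148, ratio 0.0164, interval 0.00335 to 0.0489, or log2 -3.02 with lncRNA annotations ignored) and zrt1, a zinc transporter gene (126 against 3693, log2 -5.18). tif11, which encodes translation initiation factor eIF1A, followed (log2 -4.72), with tcd1 (-4.42), SPBP4H10.17c (-4.38), rpl4101 (-4.31) and SPCC4F11.05 (-4.15). Of the wild-type reads of tcd1 and SPCC4F11.05, 4.87% and 1.27% lay past the stop codon, and with such reads alone SPCC4F11.05 was at -0.29 (interval -4.07 to 3.50), which ends its call.

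Cytosolic ribosomal protein genes were lower more often than higher. Of 139 tested, 23 were higher and 67 lower (18 and 92, then 16 and 96), the list median was 1.07 below the coding median (difference -1.07), and it lay below all 10000 random lists. rpl4101 had 812 against 13053 reads, while rpl1102 had 2504 against 26 (log2 6.29, or 3.08 with reads up to 200 nt past the gene end). The symbol rule also took in rpp40, rpp1 and rpp21, which encode subunits of ribonuclease P or MRP; rpp40 (log2 2.95) and rpp1 were higher and rpp21 was in neither class. Of 122 ribosomal protein genes in the poly(A) site test, 112 had a higher distal share and none a lower one.

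**Figure D4:**
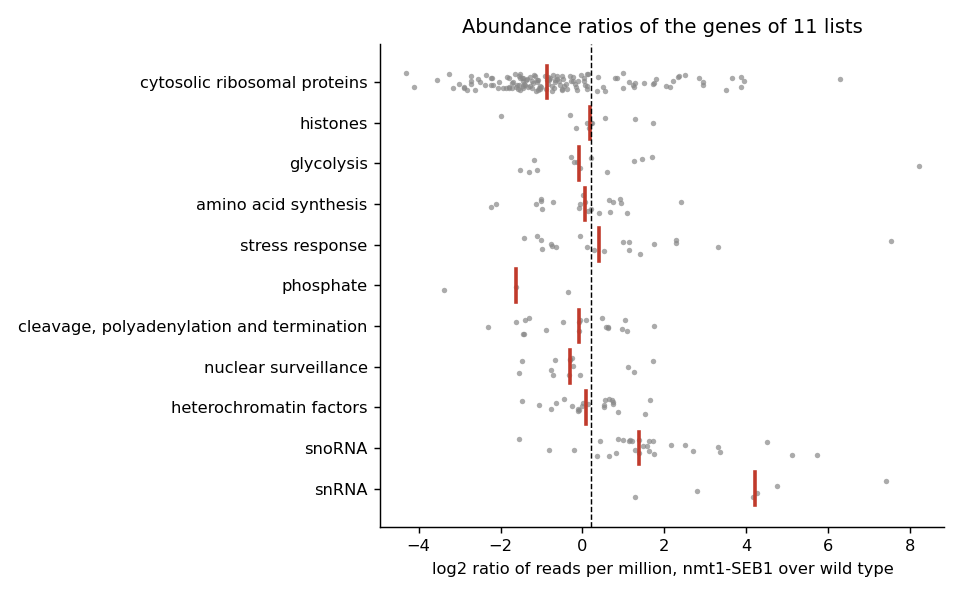
Log2 ratios of RPM, nmt1-SEB1 over wild type, for the tested genes of 11 lists (points, spread vertically for sight only), with list medians as bars and the median of all coding genes as a dashed line. Ribosomal protein genes lie mostly left of the dashed line and members of the snRNA list right of it, and all points shift left by 0.68 or 0.79 under the other scalings.

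Among lists of stress and metabolism, several held genes of both directions, and in some the more frequent direction depended on the scaling. In the stress response list 8 of 20 were higher and 3 lower (5 and 7, then 4 and 7), with hsp9 at log2 3.31 (2.40 within 200 nt of the gene end) and zym1 at 7.53, and the list median, 0.40, lay at percentile 89.5 and was -0.38 under median-of-ratios. In glycolysis 4 of 14 were higher, among them gpd3 (log2 1.70) and adh1, and 4 lower (2 and 4, then 1 and 5; percentile 68.2). Of the phosphate list, pho84 (log2 -3.37, or -2.75 with lncRNA annotations ignored) and pho1 (-1.63, or -2.45 within 200 nt of the gene end) were lower and tgp1 was not (-0.36, but -1.04 under TMM and -1.14 under median-of-ratios, where it was counted as lower; percentile 4.59). Hexose transport and glucose repression had 3 lower, such as ght1 (-1.33), and 1 higher, fbp1 (1.83), of 7 (1 and 4 under both; percentile 16.9). Iron uptake had 3 lower, among them sib2 (-2.84) and fip1 (-1.82), and 2 higher of 7 (0 and 4 under both; percentile 1.14), but its median changed sign, to 0.03, with 100 reads as the minimum. The 2 copper uptake genes ctr4 (0.66) and ctr5 (-0.06) were in neither class (percentile 49.96), but with lncRNA annotations ignored ctr4 was at 2.46 (interval 1.86 to 3.12). Amino acid synthesis had 2 of 21 higher, with ilv1 at 2.41 (1.10 within 200 nt of the gene end), and 5 lower, with lys7 at -2.23 (1 and 7 under both; percentile 58.1). The thiamine list, which holds nmt1 (0.92), had thi5 (2.08) and thi2 (1.56) higher and 1 lower of 9 (1 and 2 under both; percentile 75.6).

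Lists of RNA processing, chromatin and differentiation genes differed in direction. Of 20 cleavage, polyadenylation and termination genes, 6 were lower, with din1 at log2 -2.30 (-1.52 with sites next to A runs left out), and 3 higher, with cft2 at 1.75 (0.17 within 200 nt of the gene end; 1 and 8, then 0 and 8; list percentile 15.7), and 12 of the 15 in the site test had a higher and 1 a lower distal share. Nuclear surveillance had 3 of 14 higher and 2 lower, with rrp6 at 1.73 (0.93, and so below 2-fold, with reads past the stop codon alone, which made up 40.4% of its nmt1-SEB1 reads) and air1 at -1.56 (1 and 6, then 0 and 10; percentile 4.95). Heterochromatin factors had 2 of 22 higher, ers1 (1.64, with 2.82% of its reads past the stop codon, and 0.45, with a lower limit of -0.41, from such reads alone and the floor for wild type, which ends its call) and cid12 (1.54), and 2 lower (0 and 5, then 0 and 6; percentile 24.3). Of 10 histone genes hht2 was lower (-1.99, or -1.12 with lncRNA annotations ignored), and hht1 (1.72) was counted among 2 higher ones but was at -1.70 with reads up to 200 nt past the gene end (1 and 1, then 0 and 2; percentile 70.0). The meiotic list had 2 of 8 higher, mcp7 (1.14) and crs1 (1.13), and none lower (0 and 1 under both), at percentile 58.0. Mating and pheromone had 3 of 14 higher, with mei3 at 3.28, and 1 lower, mei2 (2 against 29 reads, ratio 0.0559, interval 0.00646 to 0.221, or log2 -2.0 with lncRNA annotations ignored; for the list 3 and 4, then 3 and 5, percentile 54.1). Sporulation had 4 of 6 higher, with spn6 at 2.36 and spn5 at 1.70, and none lower (0 and 0 under both; percentile 96.7). Near the chromosome ends, 8 of 62 genes were tested, with 3 higher, such as SPAC212.02 (3.28, or 1.11, with the floor for wild type, when sites next to A runs were left out), and 2 lower, of which SPAC977.05c had 0 against 25 reads and was at least 10.3-fold lower with the floor of 3 counts (ratio interval 0 to 0.129; for the list 2 and 3 under both, percentile 58.8). All 4 Tf2 elements tested were higher (3 under both), with Tf2-7 at 29 against 1 read (ratio 23.5, interval 3.90 to 960) and Tf2-3 at 73 against 0, at least 19.7-fold higher with that floor (lower limit of the ratio 15.6; percentile 99.99); their sequences are near-identical, so these counts are uncertain. Of 13 Tf2 elements 4 met the read minimum. The Tf2 median log2 ratio, 3.98, was 1.28 with no minimum and 1.12 with a minimum of 100 reads. Of 2233 intron-containing genes 616 were higher and 331 lower (319 and 672, then 282 and 738), with a median 0.08 above that of all coding genes (percentile 99.99), though the list median itself changed sign under TMM and median-of-ratios. Mitochondrially encoded genes could not be compared, with 6 and 8 reads on the mitochondrial contig.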

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

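Reads on a contig named MTR, outside the 3 chromosomes used in the comparisons, were above the wild-type level. The nmt1-SEB1 library had 62 reads there, 18.4 RPM over all its reads, against 18 reads or 6.66 RPM in wild type, a ratio of 2.76 (exact conditional binomial interval 1.61 to 4.95). No explanation of this difference was tested. A further contig outside the chromosomes was lower in nmt1-SEB1, at 876 against 1527 RPM.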

How the results depend on the processing

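Ignoring lncRNA annotations, counting reads past the stop codon alone, and thinning for mean position and read-through were tests chosen after the results were seen. No paired analysis was possible because there is 1 library per group and the labels give no shared replicate numbers. More distal than proximal shifts were counted under each of the 11 alternatives to the site analysis, from 8.96 distal per proximal shift with clusters chosen on wild type alone to 52.5 with the first and last clusters. Of the 1984 genes, 1881 kept a higher distal share with the deeper library thinned and 1168 with clusters chosen on wild type alone, where 31 reversed. TMM gave 1727 lower genes, 650 higher and 1549 lower coding genes and a seb1 log2 ratio of -2.15; median-of-ratios gave 1898, 575, 1700 and -2.25. This follows from the 1 factor they apply to all genes, as do the reversed medians of intron-containing genes, -0.40 and -0.51. Higher genes numbered 1662 with a minimum of 100 reads and 1557 without lncRNAs, where fewer genes are tested. The 200 nt limit gave log2 ratios of -2.36 for seb1, -0.17 for snoR02 and -1.70 for hht1, and reads past the stop codon gave -0.29 for SPCC191.04c. The iron uptake median was 0.0256 with 100 reads. Distal shifts numbered 1218 with clusters chosen on wild type alone; proximal shifts numbered 30 with the first and last clusters, 67 with 50 reads per library and 67 with 25 points. The distal share differences that reversed were those of SPBC8D2.18c (19.1 at 10 nt, 17.9 at 50 nt, 18.3 with clusters on wild type, 37.9 with first and last clusters), seb1 (-11.1 at 10 nt), dsk2 (82.6 at 50 nt, 45.0 with first and last clusters), nap1 (8.24) and act1 (29.3), both with first and last clusters; other clusters were compared there, and the cause was not tested further. With 100 reads per library, 1220 genes were longer, 36 shorter, and the median difference was 53.6 nt; without lncRNAs it was 89.8 nt. The read-through difference of 13.7 points became 19.98 at 100 nt, 5.91 at 400 nt, 17.9 with the main cluster from wild type, 17.1 without lncRNAs and 13.9 after thinning. Among other values, 392 log2 ratios of named genes stayed within their spread and 198 distal share differences kept their call. A further 168 list medians stayed within a spread taken from the random lists, which is wide for short lists. Some of these 168 medians changed sign all the same. Under median-of-ratios, histones went from 0.17 to -0.61, thiamine from 0.61 to -0.18 and mating and pheromone from 0.37 to -0.42. The meiotic list went from 0.45 to -0.33 and genes near chromosome ends from 0.41 to -0.38. The spread was exceeded by 79 ratios and 17 medians. Medians near 0 in part took the other sign there (stress response -0.38 under median-of-ratios, near chromosome ends -0.89 with no minimum). The call was lost for 7 distal share differences. Depth limits the site test: under 100 reads in a library, simulated shifts of 30 points were recovered in 51.1% of genes.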

Other observations

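The test of the 200 nt limit for adh1 and zym1 and the test of depth for the distal shifts were chosen after the results were seen; the zinc genes themselves were picked after their values were seen.

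Several genes known to respond to zinc were far apart between the libraries; no list of such genes was fixed, and the group as a whole was not tested. adh1 and the metallothionein gene zym1 were higher in nmt1-SEB1. The antisense transcript adh1AS, which overlaps adh1 on chromosome III (1590025 to 1593983, minus strand), had 70 against 4962 reads, a log2 ratio of -6.45. zrt1 and adh4 were lower, and SPBC1348.06c had 0 against 22 reads, at least 9.05-fold lower with the floor of 3 counts (ratio interval 0 to 0.148). The zinc transporter gene zhf1 was lower too (log2 -1.77), while fet4 (0.42) and loz1 (-0.51), the gene of the zinc-responsive repressor, were below 2-fold; loz1 was lower by more than that under TMM (-1.19) and median-of-ratios (-1.30).

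The DNA next to seb1 also carried a strong local signal. snu2, which lies upstream of seb1 on the opposite strand, had 3302 reads in nmt1-SEB1 and 2 in wild type at position 959555 of chromosome I, 330 nt before the start of seb1. The lncRNA SPNCRNA.2423, which overlaps the start of seb1 on the strand of snu2, had 579 reads against 1 (ratio 469, interval 83.9 to 18559). byr4, the next coding gene on the other side, had 72 against 61 reads. Position 959555 is 1 nt from the annotated start of snu2, so reads ending there hold almost none of it. The promoter that drives seb1 differs in nmt1-SEB1 by design, and no explanation of these local values was tested.

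The higher reads of adh1 and zym1 were not accounted for by reads past the gene ends alone: with reads up to 200 nt past the ends the log2 ratios were 8.08 and 5.83. A scaling factor moves all genes alike, so it cannot set adh1 and adh4 apart. Zinc supply or uptake of the 2 cultures, and an effect of Seb1 on these genes, remain open, with 1 culture each. A difference in zinc status may lie behind adh1, zym1, zrt1 and adh4.

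With the deeper library thinned there were 17.5 distal shifts per proximal one, so the excess was also seen at equal depth. Random thinning leaves the expected shares within a gene unchanged, so this test could hardly have come out otherwise. Other transcripts counted as distal sites remain open: the region searched ended at the next annotated gene, which leaves transcripts outside the annotation. A difference between the 2 library preparations remains open as well, since each group has 1 library. With these limits, the shift is consistent with an effect of low Seb1 on where transcripts end.

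Among the lncRNAs that met the read minimum, higher reads in nmt1-SEB1 were not explained by low abundance alone. The median log2 ratio of these 2840 lncRNAs was 2.87, and 95% of coding lists matched on abundance lay between 0.28 and 0.36. The size of the lncRNA median depended on that minimum, at 1.43 with no minimum and 3.43 with 100 reads. No matched lists were drawn for those 2 settings. Read-through from upstream genes may contribute, because lncRNAs overlapping or within 2000 nt downstream of another gene had a median of 3.28. A set of 1160 lncRNAs with no such gene on their strand, other lncRNAs not considered, had a median of 2.38. Of matched coding lists, 95% lay between 0.26 and 0.42. Read-through from annotated genes other than lncRNAs, overlapping or ending within 2000 nt upstream, therefore does not account for the whole. Longer read-through, and read-through from other lncRNAs, remain open.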
